A study of Bos taurus with 15 samples.

How the data were processed

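The data were RNA-seq libraries of bovine embryos at the morula stage, when the cleaving cells form a compact cluster before the blastocyst. The 15 libraries fell into 3 groups of 5: haploid androgenetic embryos, haploid parthenogenetic embryos and diploid embryos made by intracytoplasmic sperm injection (ICSI). Groups and replicate numbers were taken from the labels. Library titles begin with TII in the androgenetic, CHX in the parthenogenetic and ICSI in the diploid group. The labels gave no batch, donor, bull or day.

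Per the labels' protocols, polyadenylated RNA was amplified with a SMART-Seq HT kit and made into libraries with a Nextera XT kit. Per the submitters' processing notes, the tools were Trim Galore, cutadapt, STAR and featureCounts, with no versions. The genome build, the annotation and the strand setting of the counting were not given in the sources used here. The deposited table held raw counts per gene and library, as whole numbers that the authors had not normalized. It had 31999 rows: 27607 were named by an Ensembl identifier, 3614 by a LOC number and 778 by a gene symbol. No table pairing the Ensembl identifiers with symbols was used here, so those rows carry no gene name in the text. Of the 4392 rows without an Ensembl identifier, 3006 were matched by name to the RefSeq table of the assembly ARS-UCD2.0, which gave 80 of the LOC rows a symbol and which served for names only. Ensembl rows held 92.9% of all counts, so genes with symbols are a small part of the transcriptome. In 97 pairs of rows an Ensembl row and another row differed by at most 2% or 3 counts in every library, and 78 of the 379 symbol rows with over 1000 counts had such a partner. Whether such a pair is a gene under more than 1 name, overlapping genes or near-identical copies was not checked. Overlapping genes, near-identical copies and, since the use of strand was not given, antisense genes cannot be told apart in these counts.

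Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling factors, the default expression filter by group, a quasi-likelihood fit of all 15 libraries with 1 coefficient per group, and Benjamini-Hochberg adjustment over the 16375 rows that passed the filter, which held 99.9% of all counts. A row was called at an adjusted p under 0.05. The pairwise contrasts were androgenetic against ICSI, parthenogenetic against ICSI, and androgenetic against parthenogenetic. A further contrast set the mean of both haploid groups against ICSI. The contrast of the haploid groups is also the test of whether their differences from ICSI differ. The standard error of a log2 fold change is its size divided by the square root of F. CPM values were scaled by the TMM factors, and each mean is given with the SD over 5 libraries. Nothing in the labels says that replicates came from separate embryos, pools or animals, so p-values measure only the spread between these libraries. The biological coefficient of variation common to all rows was 1.02, which is large.

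The test was itself tested on simulated data with known changes. For androgenetic against ICSI (15571 rows) it recovered 10.4% of the rows changed 4-fold and 44.3% of those changed 16-fold. For parthenogenetic against ICSI (15683 rows) the shares were 12.9% and 40.9%, and for androgenetic against parthenogenetic (15600 rows) they were 5.26% and 45.2%. Of the calls in the simulated data, 3.64%, 0% and 2.08% were false. At this spread most changes of both sizes were missed. The false shares apply to the simulated libraries only. Some real groups held libraries far from the others, so these shares do not show how many calls are false in the real data.

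The genes to be named were fixed by rule before the data were examined. For each pairwise comparison they were the 8 largest rises and 8 largest falls among called rows with a symbol, a mean of at least 5 CPM and no overlap between the libraries of the groups compared, then called members of the fixed lists, then a set of imprinted, lineage and WNT genes whatever their result. Of that last set only SOX2, XIST and MEG3 had a row under their symbol, and MEG3 was below the expression filter. LOC rows with a RefSeq symbol counted as symbol rows. All 36 gene lists were fixed then as well. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, where at least 3 members were tested. Because most members stood under Ensembl identifiers, 2 lists reached 3 tested members, 12 had 1 or 2, and 22 had none. Families of symbol rows were drawn up after the row names had been seen.

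Library measures were compared by exact two-sided permutation tests of the difference of means over all 252 arrangements of 5 against 5, of which 0.00794 is the smallest possible p. The shares of counts in mitochondrial, ribosomal protein and X-linked genes were not analysed here, since 0 mitochondrial and 1 ribosomal protein row carried a symbol. Alternatives were DESeq2 size factors and upper-quartile factors, the DESeq2 1.42.0 Wald test, limma voom with quality weights, no filter, a filter of 5 CPM in 5 libraries, fits of the compared groups alone, the replicate number as a block, and leaving out each library. Alternatives chosen after the data were seen left out the library with fewest genes detected in each group, used genes detected as a covariate, or left out rows that duplicate an Ensembl row. Totals ranged from 19.97 to 28.98 M counts. The closest libraries of any group still differed by 64.7 times the variance of counting noise.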

Results

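Bovine morulae with only a sperm genome, only an oocyte genome, or both were compared by RNA-seq, as 5 androgenetic haploid, 5 parthenogenetic haploid and 5 diploid ICSI libraries. Androgenetic embryos develop from a sperm nucleus without the oocyte's nucleus, and parthenogenetic embryos from an activated oocyte without sperm. Each group was thus made by its own procedure, whose effects cannot be told apart from those of parental genome and ploidy. The series title names WNT signalling and cell fate in haploid androgenetic development as its subject. Mean totals were 24.5 M counts in androgenetic, 26.8 M in parthenogenetic and 23.5 M in ICSI libraries.

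Counts were more concentrated in androgenetic than in ICSI morulae. Their 20 highest rows took 15.9% ± 2.18 (SD, n = 5) of all counts, against 12.3% ± 2.76 in parthenogenetic and 10.3% ± 1.15 in ICSI libraries. The difference of 5.52 points from ICSI had an exact permutation p of 0.00794, the smallest the design allows, and an adjusted p of 0.0476 over 6 tests. Without ICSI replicate 1, 2, 3 or 4 it lost its call (exact test, adjusted p = 0.0952), at 5.49, 5.50, 5.23 and 5.36 points. The other contrasts of this share did not pass: 1.98 points for parthenogenetic minus ICSI (exact p = 0.135, adjusted 0.202) and 3.54 points for androgenetic minus parthenogenetic (exact p = 0.0714, adjusted 0.202). Genes detected averaged 16634 ± 1881 in androgenetic, 18066 ± 1108 in parthenogenetic and 18815 ± 1995 in ICSI libraries, and no pair of groups passed (exact permutation p = 0.135, 0.468 and 0.175 for androgenetic minus ICSI, parthenogenetic minus ICSI and androgenetic minus parthenogenetic). Without ICSI replicate 5, genes detected passed for both haploid groups against ICSI, at -3063 and -1631 (exact test, adjusted p = 0.0317). Without parthenogenetic replicate 6, the share of the 20 highest rows passed between the haploid groups at 4.77 points, and without ICSI replicate 5 it passed for parthenogenetic minus ICSI at 2.46 points (exact test, adjusted p = 0.0476 for each). The fewest genes detected in each group were 13564 in androgenetic replicate 6, 16154 in parthenogenetic replicate 6 and 15286 in ICSI replicate 5. The mean Spearman correlation of a library with its group was 0.68 to 0.75 in androgenetic, 0.79 to 0.87 in parthenogenetic and 0.80 to 0.89 in ICSI libraries. Androgenetic replicate 4 was closer to ICSI replicate 4 (0.846) than to any library of its own group (at most 0.792).

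**Figure D1:**
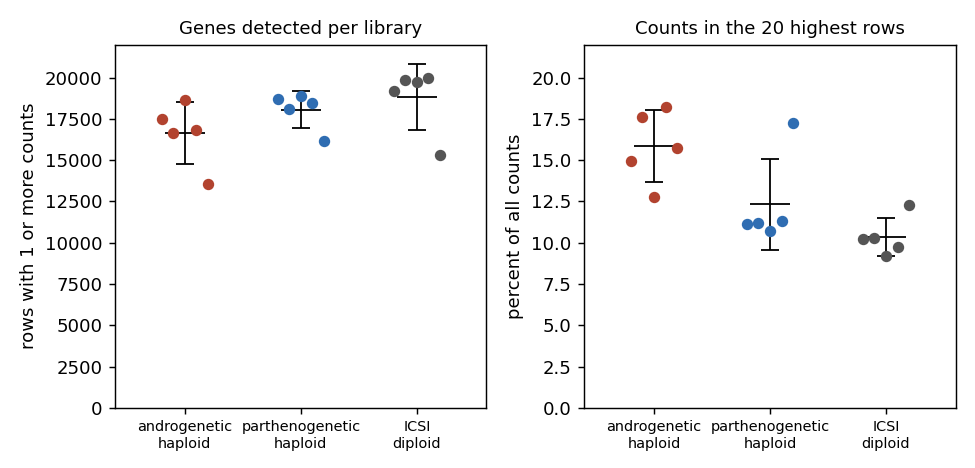
Genes detected per library (left, rows with at least 1 count) and percent of all counts in the 20 highest rows (right), by group; points are libraries, bars are means ± SD (n = 5). The androgenetic libraries sit at 12.8% to 18.2% in the right panel and the ICSI libraries at 9.22% to 12.3%.

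Androgenetic morulae differed widely from ICSI morulae. Among named genes, NWD2, a gene for a NACHT and WD repeat protein, was 26.3-fold higher, at 46.5 ± 31.6 CPM (n = 5) against 1.77 ± 1.15. TNIK, a kinase known to act on TCF-dependent transcription in WNT signalling, was 5.47-fold higher, at 2371 ± 1509.9 against 434 ± 248 CPM. The galectin gene LGALS7B was 6.49-fold higher and OST4, a small subunit of oligosaccharyltransferase, 3.90-fold higher. Counts on core histone rows rose as well: the H4 genes H4C14 (LOC516742) and H4C1 (LOC617905) were 4.91-fold and 3.62-fold higher.

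Fewer named genes fell. ASNA1, whose product inserts tail-anchored proteins into membranes, was 7.66-fold lower at 1.24 ± 0.827 against 9.53 ± 3.58 CPM. The small GTPase gene ARL15 was 6.55-fold lower, the sodium/proton exchanger family gene SLC9C2 4.36-fold lower, and TARS (TARS1), the threonyl-tRNA synthetase, 2.92-fold lower at 41.1 ± 10.8 against 120.0 ± 24.7 CPM. These were all 12 genes that met the naming rule, and their adjusted p in edgeR's quasi-likelihood test lay between 0.0270 and 0.0483. They include HIST1H2AK and HIST2H2AA4, both 5.11-fold higher, which had nearly the same counts in each library and are uncertain as separate genes. H4C14 may not be separate from them either. It had means of 2258, 1183 and 460 CPM in androgenetic, parthenogenetic and ICSI libraries, where HIST1H2AK had 1114, 569 and 218. Histone genes are near-identical copies, so reads cannot be assigned among them with certainty.

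**Figure D2:**
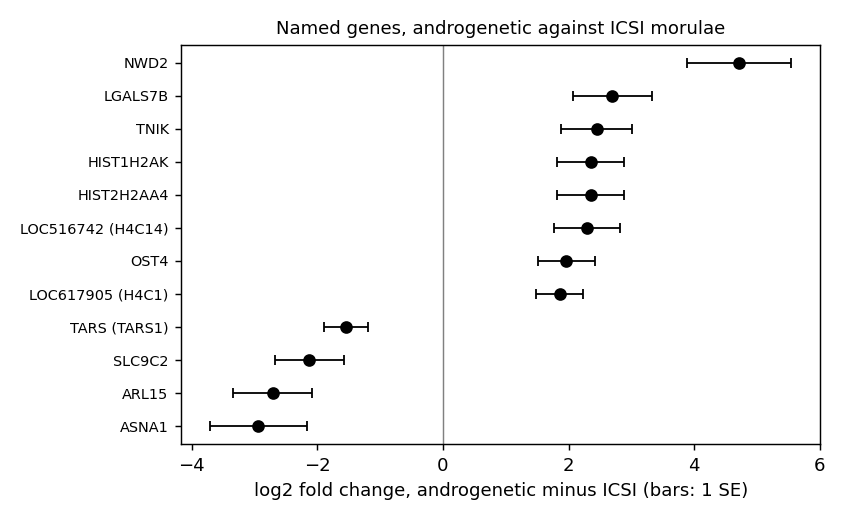
Log2 fold change of the 12 named genes in androgenetic against ICSI morulae, with bars of 1 standard error. NWD2 lies highest at 4.72 and ASNA1 lowest at -2.94.

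In all, 288 rows were higher and 173 lower at an adjusted p under 0.05 in edgeR's quasi-likelihood test, with 3231 rows at an unadjusted p under 0.05 where chance would give 819. Of the 611 tested rows with a symbol, 13 were higher and 7 lower. Among rows without a name, ENSBTAG00000005045 had the log2 fold change of 3.43 ± 0.57 (SE; adjusted p = 0.0266) and ENSBTAG00000007893 that of -2.34 ± 0.39 (adjusted p = 0.0266). With DESeq2 size factors the median of all genes moved from -0.01 to 0.13 and the calls were 372 higher and 139 lower, so the higher share went from 62.5% to 72.8%. The calls depended on which libraries were used, with 2721 to 4130 rows at an unadjusted p under 0.05 throughout. Without ICSI replicate 1, 3 or 4, or androgenetic replicate 1 or 2, there were 0 calls, without ICSI replicate 2 there was 1, and without androgenetic replicate 5 there were 9 higher and 11 lower. Without androgenetic replicate 4 there were 585 higher and 492 lower, without androgenetic replicate 6 472 and 272, and without parthenogenetic replicate 6 553 and 356. Without parthenogenetic replicate 1, 3 or 5 there were 207, 215 and 152 higher and 109, 103 and 83 lower. With genes detected as a covariate, none passed in edgeR either, with 3037 rows at an unadjusted p under 0.05. DESeq2 and limma voom called more rows in both directions, and edgeR called 1630 without the 3 libraries with fewest genes detected.

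Transcripts of aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNAs, were lower as a family in androgenetic than in ICSI morulae. Of 18 tested genes 15 had a negative log2 fold change, with a median of -1.13, and 7 were lower adjusted over the list alone, 1 of them (TARS) over all genes. Without the library with fewest genes detected in each group, 8 were lower over all genes. CARS had -2.09 ± 0.59 (SE), RARS -2.02 ± 0.61 (-2.69 without androgenetic replicate 6) and KARS -1.41 ± 0.42. The family stood below other genes in camera (adjusted p = 1.24e-04, and 0.0528 with an estimated correlation, at an unadjusted 0.0264). Histones moved the other way: 15 of 16 tested rows had a positive log2 fold change, with a median of 1.86, and 7 were higher adjusted over the list alone, 5 of them over all genes (camera adjusted p = 9.76e-08, and 0.0248 with an estimated correlation). With DESeq2 size factors the medians were -0.995 and 1.98, and with upper-quartile factors -1.09 and 1.90. The 5 histone rows called over all genes include HIST1H2AK and HIST2H2AA4, which had nearly the same counts in each library, and H4C14, whose group means kept nearly their proportions. The row counts and camera took them as separate members. The libraries were made from polyadenylated RNA, and whether the histone counts follow all histone RNA was not checked. Both families were chosen after the row names were seen.

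**Figure D3:**
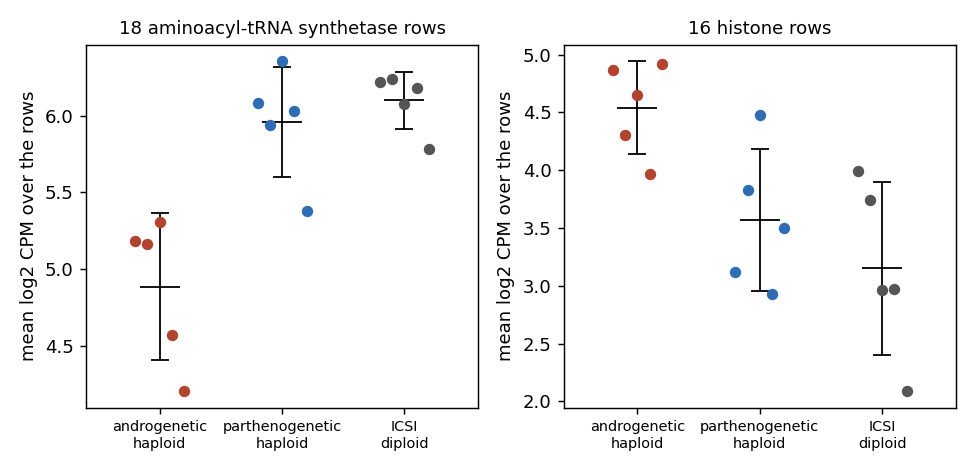
Mean log2 CPM over 18 aminoacyl-tRNA synthetase rows (left) and 16 histone rows (right), by group; points are libraries, bars are means ± SD (n = 5). The androgenetic libraries reach at most 5.31 for the synthetases, below the lowest of the other groups at 5.38.

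By edgeR's calls, parthenogenetic morulae differed from ICSI morulae in few rows, all of them lower. SNURF, an imprinted gene transcribed from the paternal allele in mammals, stood at 0.701 ± 0.653 CPM (n = 5) in parthenogenetic against 120.3 ± 48.1 in ICSI and 213 ± 62.3 in androgenetic libraries. It was 170.4-fold lower than in ICSI (log2 fold change -7.41 ± 0.75 SE, adjusted p = 8.33e-05). ULBP27, of the family of stress-induced ligands of the NKG2D receptor, was 322-fold lower (-8.33 ± 1.38, adjusted p = 0.0187), at 0.0804 ± 0.122 against 28.2 ± 26.3 CPM. The size for ULBP27 rested on few libraries: without parthenogenetic replicate 3 it was 865-fold, and without ICSI replicate 1 it was 189-fold and lost its call (edgeR adjusted p = 0.0670).

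edgeR's quasi-likelihood test called 12 rows lower and 0 higher, and 304 rows had an unadjusted p under 0.05, fewer than the 819 of chance. DESeq2 called 35 lower and 0 higher (510 rows at an unadjusted p under 0.05), and limma voom called 27 lower and 2 higher (1069 such rows). A simulation with no changed gene gave 614 such rows in edgeR. The edgeR fit shared its estimate of spread with the androgenetic libraries, which were less alike than the others. Few calls therefore do not show that parthenogenetic and ICSI morulae were alike. SNURF and ULBP27 were the only symbol rows among the 12, and the unnamed ENSBTAG00000008251 (-7.87 ± 0.74) and ENSBTAG00000032079 (-7.41 ± 0.77) had the lowest adjusted p beside SNURF (5.20e-05 and 8.33e-05). ENSBTAG00000008251 followed SNURF across the androgenetic and ICSI libraries (correlation of log2 CPM of at least 0.9). These rows may therefore not be separate signals. Reads of SNURF cannot be told from those of SNRPN, which shares its transcript, and ULBP27 has near-identical copies, so both are uncertain as single genes. Without parthenogenetic replicate 1, 2 or 6 the number lower was 3, and without parthenogenetic replicate 5 it was 4. Leaving out each library in turn, SNURF passed in 15 of 15 fits and ULBP27 in 10.

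Between the haploid groups, SNURF was 301-fold higher in androgenetic morulae (log2 fold change 8.24 ± 0.78 SE, adjusted p = 2.30e-05). SEPT10 (SEPTIN10), of the septin family of filament-forming GTPases, was 86.1-fold higher at 98.9 ± 112 against 1.14 ± 1.38 CPM, but 48.6-fold without androgenetic replicate 6 and 178-fold without parthenogenetic replicate 5. PTPN20, a tyrosine phosphatase gene, was 9.24-fold higher, NWD2 8.71-fold, the ubiquitin ligase gene MARCH1 (MARCHF1) 8.69-fold and LGALS7B 6.89-fold. Without parthenogenetic replicate 6, NWD2 was 19.2-fold higher. ARL15 was 7.87-fold lower and TARS 3.01-fold lower in androgenetic morulae, at 41.1 ± 10.8 against 124 ± 48.5 CPM for TARS. The synthetase family had a median of -1.05 with 15 of 18 negative and 7 lower adjusted over the list alone (camera adjusted p = 2.95e-04, and 0.0861 with an estimated correlation), and the histones had a median of 0.97 with 15 of 16 positive (1.70e-04, and 0.0861). Both medians kept their sign under the other scaling factors.

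The long non-coding RNA XIST, which coats the inactive X chromosome, averaged 13.9 ± 8.46 CPM (n = 5) in androgenetic, 51.6 ± 25.6 in parthenogenetic and 24.6 ± 16.3 in ICSI libraries. The difference of the haploid groups (-1.89 ± 0.68) did not pass over all genes (edgeR adjusted p = 0.142) and passed adjusted over the list alone (0.0128), where it was the only tested member of its list. Neither difference from ICSI passed: -0.83 ± 0.67 for androgenetic (adjusted p = 0.530) and 1.07 ± 0.67 for parthenogenetic (unadjusted p = 0.129 in edgeR). SOX2, a pluripotency factor, was near 2.50 CPM in androgenetic, 4.84 in parthenogenetic and 2.58 in ICSI libraries. Its log2 fold changes were -0.05 ± 0.88, 0.91 ± 0.89 and -0.95 ± 0.89 for androgenetic minus ICSI, parthenogenetic minus ICSI and androgenetic minus parthenogenetic, and none passed. The sign of the first turned under 6 alternatives, and also without ICSI replicate 2 or 4 or androgenetic replicate 1 or 6. Without androgenetic replicate 2 the first was -0.71 and the third -1.64, and neither passed.

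**Figure D4:**
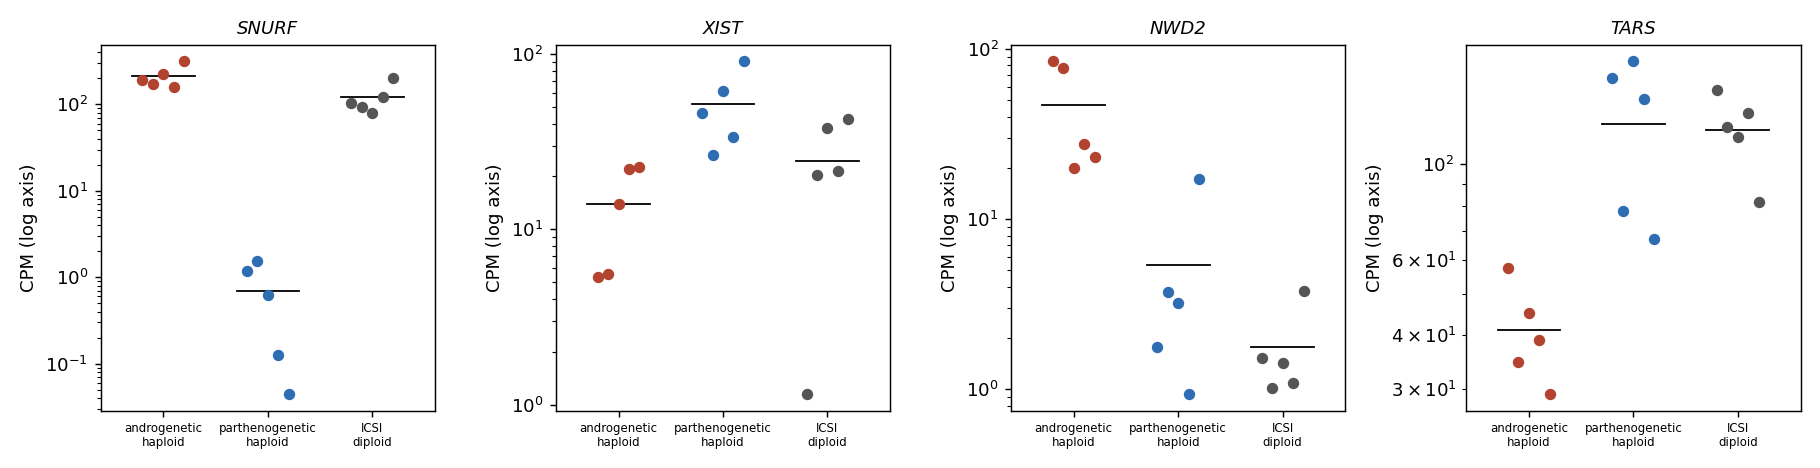
CPM per library of SNURF, XIST, NWD2 and TARS on log axes, by group; points are libraries and lines are group means. All 5 parthenogenetic libraries lie at or below 1.54 CPM of SNURF, and the androgenetic and ICSI libraries at or above 79.1 CPM.

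For androgenetic against parthenogenetic morulae, edgeR's quasi-likelihood test called 150 rows higher and 137 lower, with 3056 at an unadjusted p under 0.05. ENSBTAG00000008251 (8.46 ± 0.76) and ENSBTAG00000005045 (7.07 ± 0.68) rose with SNURF at the lowest adjusted p (2.30e-05), and ENSBTAG00000007893 fell by 2.53 ± 0.39 (adjusted p = 0.00872). Of these, ENSBTAG00000008251 followed SNURF across libraries and may not be a signal separate from it. With DESeq2 size factors the median of all genes moved from 0.00 to 0.12 and the higher share from 52.3% to 62.1%. Without parthenogenetic replicate 1 the test called 7 higher and 7 lower, without replicate 3 it called 12 and 8, without replicate 5 it called 15 and 11, and without replicate 6 it called 506 and 397. Without androgenetic replicates 1, 2, 4 and 5 in turn it called 57, 69, 338 and 58 higher and 30, 36, 400 and 41 lower. Without ICSI replicates 1 to 5 in turn it called 104, 80, 90, 67 and 256 higher and 63, 57, 60, 37 and 184 lower. A fit of these 2 groups alone called 22 and 5, and SNURF was the only named gene that passed without each of the 15 libraries.

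Taken as a mean, the haploid groups shared little against ICSI. edgeR's quasi-likelihood test called 6 rows lower and 0 higher, with 1476 at an unadjusted p under 0.05, while DESeq2 called 151 higher and 40 lower (1958 such rows) and limma voom 109 higher and 75 lower (3314 such rows). Without androgenetic replicate 4 the number lower was 10, without ICSI replicate 5 it was 2, and without androgenetic replicate 1 or 5, parthenogenetic replicate 1, 2, 3 or 6, or ICSI replicate 1, 2, 3 or 4 it was 3. Only ENSBTAG00000032079 was lower in both comparisons (-2.47 in androgenetic and -7.41 in parthenogenetic morulae, and -4.94 ± 0.52 as a mean, adjusted p = 2.59e-04). It was not shared without any 1 of ICSI replicates 1 to 5, parthenogenetic replicates 1, 2 and 5 or androgenetic replicates 1, 2 and 5, where 0 rows were shared, and without androgenetic replicate 4 there were 2. Independent lists of these sizes would share 0.127 lower rows and 0 higher rows, and simulated unchanged groups shared 0. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.237 and the covariance 0.311. Simulated unchanged groups set against shared simulated ICSI libraries gave a correlation of 0.500 and a covariance of 0.489. All simulated libraries were drawn with a spread estimated over the 3 groups together, so these values are no like reference for the real ICSI libraries. The spread of the real ICSI libraries alone gives a covariance of 0.343, near the observed value. With the ICSI libraries split between the comparisons, the correlation lay between -0.09 and 0.14 and 0 rows were shared in all 10 splits.

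SNURF was the only imprinted gene under a symbol that passed over all genes. The paternally expressed list had 3 tested members. In parthenogenetic against ICSI morulae SNURF was lower and USP29 and MKRN3 had 0.83 and 0.74, so the median of 0.74 and the mean of -1.95 differ in sign. The list was called lower (camera adjusted p = 6.49e-07, and 4.73e-04 with an estimated correlation) through SNURF alone. In androgenetic against parthenogenetic morulae it was called higher (8.46e-04, and 0.00783), with SNURF as the only member that passed, and in androgenetic against ICSI morulae it was not called (0.265, and 0.310 with an estimated correlation). Of the maternally expressed list, MEG8 had 4.09 in parthenogenetic against ICSI morulae, which passed adjusted over the list alone (0.0412) as the only tested member and not over all genes. It had 2.15 and -1.93 in androgenetic against ICSI and parthenogenetic morulae, and neither passed. Its androgenetic counts were all in replicate 4 (78), and without that library the values were -4.77 and -8.85, of which the second passed over all genes (edgeR adjusted p = 0.0353). MEG3, below the expression filter, had 161, 0, 92, 105 and 0 counts in the parthenogenetic libraries, 0, 19, 1, 0 and 0 in the androgenetic libraries and 0 in all 5 ICSI libraries, where a count of 0 allows up to 3 counts each.

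Genes of embryonic genome activation were represented by the homeobox genes ARGFX and DUXA and by TAF7. In androgenetic against ICSI morulae ARGFX had a log2 fold change of 1.49 ± 0.50 and DUXA 2.69 ± 1.03, and both passed adjusted over the list alone (0.0240 and 0.0260) and not over all genes (0.1004 and 0.147 in edgeR). In androgenetic against parthenogenetic morulae they had 1.42 and 4.02 and again passed adjusted over the list alone (0.0160 and 0.00499) and not over all genes. TAF7 had 0.22 ± 0.43 against ICSI (unadjusted p = 0.611 in edgeR; -0.34 without androgenetic replicate 6) and -0.06 ± 0.43 against parthenogenetic morulae (0.895), where the sign turned without androgenetic replicate 1, 2 or 5 or parthenogenetic replicate 5. DUXA stood at 6412 CPM in androgenetic replicate 6, the library with fewest genes detected, and at 86.2 to 471 CPM in the other 4 androgenetic libraries. Without that library its log2 fold changes were -0.06 against ICSI and 1.28 against parthenogenetic morulae, and without ICSI replicate 5 the first was 3.57. Without androgenetic replicate 5 the list passed in camera against ICSI (0.0427) and against parthenogenetic morulae (0.0214). With all libraries it was not called in any comparison (camera adjusted p = 0.165, 0.831 and 0.0801 for androgenetic minus ICSI, parthenogenetic minus ICSI and androgenetic minus parthenogenetic).

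WNT genes were hardly covered by named rows. In androgenetic against ICSI morulae PYGO2 had -0.81 and TLE1 -0.45, the only tested WNT transducers, and PLCB3 of the calcium arm had -0.17. These values rested on few libraries: TLE1 had -4.19 without androgenetic replicate 2 and 0.0142 without replicate 6, PYGO2 had 0.79 without ICSI replicate 5 and -1.95 without androgenetic replicate 1, and PLCB3 turned to 0.25, 0.0852 and 0.24 without ICSI replicate 2 and androgenetic replicates 2 and 6. With all libraries none of them passed in any comparison, whether adjusted over the list alone or over all genes. TNIK, higher in androgenetic morulae, was in no fixed WNT list. The ribosomal protein gene RPL31 had 1.12 against ICSI and 1.11 against parthenogenetic morulae, which did not pass over all genes. It passed adjusted over the list alone (0.00283 and 0.00310) as the only tested member, so these values are unadjusted p from edgeR. Without the 3 libraries with fewest genes detected it passed over all genes in both (edgeR adjusted p = 0.0197 and 0.0139). CEBPG of the integrated stress response had 1.44 in androgenetic against parthenogenetic morulae, which did not pass over all genes. It too was the only tested member of its list, so its value adjusted over the list alone (0.0101) is an unadjusted p from edgeR. SOHLH1 (oocyte transcripts), MAD2L1 (mitosis), CNTRL (centrosome), BIK (apoptosis), and CYR61 and CTGF (HIPPO targets) were the only tested members of their lists and passed in no comparison. The other 22 lists had no tested member, among them the trophectoderm, hypoblast, Y-linked, cumulus cell and sperm lists.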

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

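The contrast of the haploid groups for named genes and the search for libraries far from their group were fixed before the data were seen, and the tests of the 3 patterns and of the groupings were chosen after, all but the covariate test of the synthetases also after the result they measure.

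Libraries were compared with the other 4 of their group for 3 groups and each named gene or library measure. Of 66 such groups 11 held a library far from the others, where about 3.3 would by chance. Parthenogenetic replicate 6 had 16154 genes detected, 17.2% of counts in its 20 highest rows, 17.1 CPM of NWD2 and 1499.8 CPM of OST4. ICSI replicate 5 had 15286 genes detected, 3.79 CPM of NWD2, 103 CPM of SEPT10 and 12.1 CPM of PTPN20. Androgenetic replicate 6 had 291 CPM of SEPT10. ULBP27 stood at 75.1 CPM in ICSI replicate 1 and at 0.292 CPM in parthenogenetic replicate 3.

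The haploid groups differed in their distance from ICSI for 7 of 14 named genes. All 14 were named for a call against ICSI with the same libraries, which raises this share. Over all 16375 rows, 287 were called between the haploid groups. The difference of log2 fold changes, androgenetic minus parthenogenetic, was 8.24 for SNURF, 7.49 for ULBP27, 3.12 for NWD2 and 2.79 for LGALS7B. It was -2.98 for ARL15, -2.28 for SLC9C2 and -1.59 for TARS.

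The first pattern weighed was the 12 rows lower in parthenogenetic libraries, which form 7 separate profiles. Shallower parthenogenetic libraries could not account for it, since their mean total was 3.26 M counts above that of ICSI. A transcript of all 12 rows made from every paternal genome was left open: 6 rows were under 1 CPM in at least 1 androgenetic library, but all 6 were so in androgenetic replicate 2, and without it 3 remained. Paternal sequence carried by only part of the sperm, such as the Y chromosome, was left open too. In the same 6 rows the ICSI library with least XIST had the highest CPM of the ICSI libraries, which could come from that library alone, and against the explanation all 5 ICSI libraries had at least 8.47 CPM of each, unless libraries were pools.

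The second pattern was the number of rows called for the androgenetic libraries. The 3 libraries with fewest genes detected in their groups could not by themselves account for it, since 1630 rows were called against ICSI without them. The remaining androgenetic libraries still had 16665 to 18633 genes detected and the remaining ICSI libraries 19196 to 19950. That fit therefore cannot set aside few genes detected in the other androgenetic libraries. The number of genes detected, whatever the group, was left open: a split of androgenetic and parthenogenetic libraries by genes detected called 1339 rows against 287 for the true groups, and that of androgenetic and ICSI libraries 379 against 461, but each shared 4 of 5 libraries with the androgenetic group. With genes detected as a covariate 0 rows were called against ICSI, and 3037 had an unadjusted p under 0.05 against 3231 without it.

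The third pattern was lower synthetases and higher histones in androgenetic libraries. Scaling between libraries could not account for it, since the smallest synthetase median in size under the other factors was -0.995, and the histone medians were 1.98 and 1.90. The 3 libraries with fewest genes detected in their groups could not by themselves account for the synthetases, at -1.11 without them. Nor could they account for the whole rise of the histones: 16 of 17 rows stayed positive and 7 were called, against 5 with all libraries. The histone median was 1.51 (MAD 1.05) against 1.86 (MAD 0.91). The histone family itself kept its camera p at the preset correlation (5.16e-05) and not with an estimated correlation, which went from 0.00796 to 0.0516 with fewer libraries. With the number of genes detected as a covariate, the synthetase median was -0.78 (MAD 0.75), against -1.13 without it (camera p = 1.54e-04, and 0.00483 with an estimated correlation). In each group the library with fewest genes detected had the lowest synthetase mean (log2 CPM 4.20 in androgenetic, 5.38 in parthenogenetic, 5.78 in ICSI). Genes detected also differed in mean between the groups, so a covariate cannot set how much of the size it accounts for. TARS, the 1 synthetase called with all libraries, went from -1.54 ± 0.35 (SE) to -1.13 ± 0.33 with the covariate and lost its call. The histones had a median of 2.08 (MAD 0.77) with the covariate (camera p = 9.20e-07, and 0.0225 with an estimated correlation). Their median did not shrink with it, but 0 rows were called against 5. The median log2 fold change of these 5 rows went from 2.35 to 2.26 and their median standard error from 0.54 to 0.66. The 5 include HIST1H2AK and HIST2H2AA4, which had nearly the same counts, and H4C14, whose group means kept nearly their proportions. Transcript length and the polyadenylated share of histone RNA were not tested.

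For each comparison 100 groupings of the same libraries were fitted, and every count given here includes the true grouping. By rows called, the true grouping of parthenogenetic and ICSI libraries gave 12 and the highest other 2, so 1 grouping of 100 gave as many and chance was unlikely for the calls. By rows at an unadjusted p under 0.05 chance was left open, since 37 groupings had at least the true 304, up to 652. For androgenetic against ICSI the true grouping called 461 rows and the highest other, the split by genes detected, 379. By either count only 1 grouping of 100, the true 1, reached its value, so chance was unlikely. The split by genes detected came near by rows at an unadjusted p under 0.05 too (3067 against 3231). So neither count tells the groups from the number of genes detected. For androgenetic against parthenogenetic the true grouping called 287 rows and the highest other 1339, and 2 groupings reached the true value by either count. Few groupings did so, but that with 1339 was the split by genes detected. These counts therefore do not tell the groups from the number of genes detected. For both haploid groups against ICSI the true grouping called 6 rows and the highest other 1340. By calls 3 groupings reached the true value, and by rows at an unadjusted p under 0.05 8 did. The other groupings also mixed the haploid groups at random, which the true grouping did not. They are therefore no like reference, and chance was left open for this contrast. The groupings with 1339 and 1340 calls joined libraries with few genes detected, which points to a structure of the samples.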

How the results depend on the processing

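All settings named here that leave out 3 libraries, add genes detected or drop duplicate rows were chosen after the data were seen. SNURF kept its call and direction under every setting. There were 5 libraries a group and the biological coefficient of variation was 1.02. Whether spread or depth limits the calls was not tested. Except where a setting tests fewer libraries or genes, the cause of a change was not tested.

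For androgenetic against ICSI, genes higher (288) and lower (173) were 1252 and 735 in DESeq2 and 976 and 755 in limma voom. The stricter filter gave 587 higher and no filter 77 lower. Without the 3 libraries with fewest genes detected they were 990 and 640, and with genes detected as a covariate 0 and 0. Leave-one-out values ran from 0 to 585 higher and from 0 to 492 lower.

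For parthenogenetic against ICSI, DESeq2 called 35 lower, and limma voom 27 lower and 2 higher. Without the 3 libraries 6 were lower, and leave-one-out values ran from 3 to 14. For androgenetic against parthenogenetic, higher (150) and lower (137) were 979 and 686 in DESeq2, 970 and 817 in limma voom, 22 and 5 in a fit of these groups alone, 1071 and 803 without the 3 libraries, and 98 and 56 with the covariate. The stricter filter gave 251 higher and no filter 62 lower. Leave-one-out values ran from 7 to 506 higher and from 7 to 400 lower. For both haploid groups against ICSI, DESeq2 called 151 higher and 40 lower, limma voom 109 and 75, 3 were lower without the 3 libraries, and leave-one-out values ran from 2 to 10 lower. The overlap (1) was 4 in limma voom, 0 with the covariate, 0 in each of 10 splits of the ICSI libraries and 0 to 2 in leave-one-out fits.

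With the replicate number as a block there were 0 higher and 0 lower for androgenetic against ICSI, 3 lower for parthenogenetic against ICSI, 44 and 44 for androgenetic against parthenogenetic, 1 lower for both haploid groups, and an overlap of 0. Of the named results 19 lost their call, and the list tests did not change. Replicates shared only a number: the own number correlated best in 2 of 4 androgenetic and 1 of 4 parthenogenetic libraries against ICSI, and in 0 of 4 between the haploid groups.

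SOX2 in androgenetic against ICSI morulae (-0.05) turned to 0.11 with DESeq2 size factors and in DESeq2, 0.0228 with upper-quartile factors, 0.0429 with no filter, 0.18 without the 3 libraries and 0.38 with the covariate, and leave-one-out values ran from -0.71 to 0.37. Without the 3 libraries, genes detected passed at -2296 for androgenetic and -1153 for parthenogenetic minus ICSI, and the share of the 20 highest rows at 1.23 points for parthenogenetic minus ICSI and 4.80 for androgenetic minus parthenogenetic (exact test, adjusted p = 0.0343). Leave-one-out differences in genes detected ran from -3063 to -1414 and from -1631 to -270.3 against ICSI. Those of the share ran from 4.92 to 6.28 points for androgenetic minus ICSI, 0.750 to 2.46 for parthenogenetic minus ICSI and 2.94 to 4.77 between the haploid groups. The embryonic genome activation list had leave-one-out adjusted p from camera of 0.0427 to 0.609 for androgenetic and 0.448 to 0.860 for parthenogenetic against ICSI, where its direction turned in some fits and without the 3 libraries (0.570), and of 0.0214 to 0.439 between the haploid groups. Shares without mitochondrial rows were not run.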

Other observations

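All tests in this part were chosen after the row names and values had been seen.

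As families, rows of non-coding genes stood above other genes in androgenetic morulae, with few rows called with all libraries. Among 826 RefSeq long non-coding RNA rows the median log2 fold change against ICSI was 0.83, with 25 rows higher and 2 lower over all genes (camera adjusted p = 3.05e-04, and 0.0248 with an estimated correlation). Against parthenogenetic morulae the median was 0.64, with 19 higher and 1 lower (2.95e-04, and 0.0386). With genes detected as a covariate 0 of these rows were called against ICSI, at a median of 0.99, and 7 higher and 1 lower against parthenogenetic morulae. Without the 3 libraries with fewest genes detected, 94 were higher and 18 lower against ICSI, and 102 and 21 against parthenogenetic morulae. All rows without an Ensembl identifier took 8.66% ± 0.81 of counts in androgenetic, 6.39% ± 0.80 in parthenogenetic and 6.32% ± 0.38 in ICSI libraries. The families were not set against these rows alone. The 16 nuclear tRNA rows had medians of 1.52 against ICSI (0.00229, and 0.0248) and 1.38 against parthenogenetic morulae (0.00189, and 0.0386), with 1 and 0 rows called over all genes. With the covariate 0 were called in either, at medians of 1.04 and 1.42. Each of these medians kept its sign under the other scaling factors. The libraries were made from polyadenylated RNA, and whether reads on the tRNA rows came from tRNAs was not checked. Septins, which form filaments at the cleavage furrow, were not called as a family against ICSI (camera adjusted p = 0.199), although SEPT10 was higher in androgenetic than parthenogenetic morulae.

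ENSBTAG00000005045 differed between all groups: 45.5 ± 19.6 CPM (SD, n = 5) in androgenetic, 4.24 ± 2.49 in ICSI and 0.333 ± 0.199 in parthenogenetic libraries. It was the only row called higher in androgenetic and lower in parthenogenetic morulae against ICSI (3.43, adjusted p = 0.0266, and -3.65, adjusted p = 0.0148, in edgeR), and 0 rows were called in the opposite order. It was singled out for this order, and no explanation of it was tested.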
